A study of Mus musculus and Drosophila melanogaster with 10 samples.

How the data were processed

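The labels listed 10 samples in 10 groups. ExoCAGE and 3' RNA-seq of mouse bone marrow-derived dendritic cells at 0, 2 and 4 h of LPS, and 3' and full-length RNA-seq of fly heads, were taken from the deposited processed files. Groups came from the labels. The thymocyte sample among these had no table in the files and was not analysed here, and 2 per-sample columns in the mouse tables belonged to a time point of no listed sample and were not used. The mouse reads were aligned with TopHat 1.4.1 to mm9 and the fly reads with dm3, per the submitters' processing notes. The counting tool and annotation are not given in the sources used here.

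The mouse gene tables held a signal, read counts per gene that the authors had divided by 1 size factor per column, as deposited. The column names number the libraries of a time rep1 and rep2, and the labels list 1 sample for them. How the size factors were made is not given in the sources used here. Every value of each column was a whole multiple of its smallest value above 0, so 100% of values gave whole reads at a tolerance of 1e-06. The ExoCAGE libraries held 3362150 and 3030644 reads at 0 h, 3399394 and 3722671 at 2 h and 3158401 and 3643360 at 4 h. The 3' libraries held 8804788 at 0 h, 8773422 and 8568630 at 2 h and 7252187 and 8204977 at 4 h. The most abundant gene took 2.33 to 6.61% of ExoCAGE reads and 3.92 to 4.22% of 3' reads. The libraries of a time correlated at 0.961 to 0.985 (Pearson, log2 scale). The fly full-length signal was deposited as reads per base pair of a gene, per the file headers, with no depth stated, so depth is unknown. The design had assumed another unit for it. The fly 3' score was made by the authors with their ESAT software, per the file headers, and 95.7% of scores were whole. The ExoCAGE window lists held a gene and a window of 5 bases per file as deposited by the authors, with no score or strand and with a threshold that is not given in the sources used here.

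Each gene identifier was given its mouse symbol from the supplied name tables: of 20381 identifiers, 19990 had 1 symbol, 141 several and 250 none, and 217 shared a symbol with another. Gene order came from the GRCm38.p6 gene table and was used only for neighbours. A gene was called higher or lower when log2(value + 1) differed by at least 2-fold the same way in every pairing of libraries and the mean of the higher time was at least 10 normalised reads. Fold changes on this scale understate the change of genes with few reads. With 1 sample per group no test of the conditions was made. The same rule was applied to splits that mixed the times, which gives the level from library to library for genes that changed little with time. With 2 libraries at each time, the pairings across times run in opposite directions within a split. A gene that changed with time can therefore hardly be called there. At 3' ends against 0 h, with 1 library at 0 h, a pairing of each split is itself a contrast of times, so those splits do not give that level alone. A gene at 0 reads in a time was compared with a floor of 3 reads over the group, and a gene with 1 to 3 reads was given the ratio of pooled reads with its exact 95% interval. Reads came from PCR without molecular identifiers, so intervals and floors cover counting error only. Reads of near-identical gene copies were not resolved.

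Before the data were examined, 22 mouse gene lists and 13 fly lists, the calling rule and the genes to name were fixed. Named were the 8 largest increases and 6 largest decreases against 0 h in each assay, ranked by the smallest change over pairings, up to 4 members of each list with at least 3 measured members, members that went against their list, and the 5 largest gaps each way between assays. The mouse lists covered cytokines and chemokines, interferon-stimulated genes, immediate-early genes, NF-kB genes, maturation genes, MHC class I and class II, TLR signalling, cell cycle, cholesterol synthesis, glycolysis and hypoxia, lysosome, ribosomal proteins, and markers of dendritic cells, macrophages, neutrophils, T cells, B cells, NK cells, mast cells, erythroid cells and stromal cells. A list's median was placed among 10000 random lists of the same size matched on level (seed 20). Fly genes were called higher or lower at 2-fold with a pseudocount and a minimum of 1 read per base pair. Windows of 5 bases were read as half-open and shared when they overlapped by 1 base. Other choices of pseudocount, minimum level, fold, correlation and overlap were run as alternatives. So was a median-ratio rescaling, which scales each library by the median ratio of the genes read in all libraries.

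Added after the data were seen were a rescaling of every library to the same total of reads, the leaving out of genes held almost wholly by 1 library (at least 30 normalised reads and 16 times the highest other library plus 1), a lower fly pseudocount, edgeR 4.0.16 and limma. The edgeR quasi-likelihood test ran on the recovered reads without the second 2 h column of each mouse table, left out by choice because its step lay near 1, at an adjusted p of 0.05, with 2 residual degrees of freedom for ExoCAGE and 1 for 3' RNA-seq. It treats libraries as replicates, assumes that a lone library varies like the others, and speaks of the libraries, not the conditions. Of the genes called at 4 h against 0 h, 1702 of 1716 higher and 1102 of 1113 lower in ExoCAGE passed it, as did 1635 of 1677 and 1389 of 1453 at 3' ends. At 2 h against 0 h, 997 of 1122 and 486 of 739 passed in ExoCAGE and 1182 of 1239 and 868 of 1148 at 3' ends. At 4 h against 2 h, 298 of 413 and 152 of 241 passed in ExoCAGE and 518 of 574 and 292 of 338 at 3' ends. For ExoCAGE it was also run with the number in the column name as a block, and limma was run on log2(value + 1) of every library with and without that block, at the same adjusted p.

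The rule was tested on simulated data for 4 h against 0 h. In ExoCAGE, over 8984 genes, it found 4 of 50 genes changed 2-fold and 50 of 50 changed 4-fold, 8-fold or 16-fold, with 3 false calls. At 3' ends, over 10027 genes, it found 16 of 50 at 2-fold and 50 of 50 at each larger fold, with 29 false calls. Among 2370 simulated fly genes, 0 of 50 changed 2-fold and 50 of 50 changed 4-fold were found. The edgeR run found 38 of 50 and 45 of 50 genes at 2-fold. A planted shift of 1 in log2 was found in 20 of 20 lists and a shift of 0 in 0 of 20. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.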

Results

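The study read the ends of transcripts in mouse bone marrow-derived dendritic cells, antigen-presenting cells grown here from C57BL/6J marrow in GM-CSF, before and after lipopolysaccharide (LPS), the bacterial component sensed through TLR4. ExoCAGE placed reads at 5' ends after an exonuclease step, and 3' RNA-seq placed reads next to the poly(A) tail. Both assays covered 0, 2 and 4 h of LPS. Fly heads were read at 3 and 15 h of zeitgeber time, the clock that counts hours from lights on. The labels named 10 samples in 10 groups, so n = 1 per group. No difference between conditions below has a p-value. Each mouse time point held 2 libraries, except the 3' 0 h time point with 1. The table headers number them rep1 and rep2, the labels list 1 sample for them, and neither says whether they are separate cultures. They were read as libraries of 1 sample. The ranges given in parentheses run over the pairings of these libraries, unless they belong to a share or are called an interval. ExoCAGE libraries held 3030644 to 3722671 reads on genes and 3' libraries 7252187 to 8804788. The thymocyte sample was not analysed here.

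ExoCAGE first asked which transcripts differed at their 5' ends 4 h after LPS. Interferon-induced antiviral genes and inflammatory mediators stood highest over 0 h. The chemokine gene Cxcl10 had a log2 fold change of 10.57 (10.45 to 10.68), the cytokine gene Il6 10.29 (9.85 to 10.74) and the oligoadenylate synthetase-like gene Oasl1 10.26 (10.18 to 10.34). The mitochondrial nucleotide kinase gene Cmpk2 stood at 10.71 (9.87 to 11.56), the guanylate-binding gene Gbp5 at 9.77 (9.67 to 9.87) and the antiviral genes Ifit2, Ifit1 and Rsad2 at 9.70, 9.83 and 9.37. The steepest fall was in Smim19, which encodes a small membrane protein, at −8.30 (−8.45 to −8.14). The lysophosphatidic acid receptor gene Lpar5 was at 0 reads at 4 h and so at least 24.3-fold lower, against a floor of 3 reads over the group. On the same floor the metallopeptidase gene Amz1 was at least 24.4-fold lower, C130050O18Rik at least 19.2-fold, Gramd4 at least 14.3-fold and 6430548M08Rik at least 13.1-fold.

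All 37 measured members of the fixed list of interferon-stimulated genes were higher at 4 h in ExoCAGE, with a median log2 fold change of 5.50, above 100% of 10000 random lists matched on level. Of 34 cytokine and chemokine genes, 32 were higher, with a median of 5.10, or 5.05 with 3 genes at 0 reads set to their bound. These included Ptgs2, the inducible cyclooxygenase, at 9.11 (8.38 to 9.85) and Nos2, the inducible nitric oxide synthase, at 8.91 (8.31 to 9.51). Of 24 NF-kB feedback and survival genes, 19 were higher, with a median of 2.20. The NF-kB regulator genes Nfkbiz, Nfkbia and Nfkbib stood at 5.92, 5.01 and 4.05, and Cflar, which restrains caspase-8, at 3.95. Of 18 dendritic cell maturation genes, 16 were higher, with a median of 2.96. The costimulatory receptor gene Cd40 stood at 8.93 (8.59 to 9.26), the cytokine signalling suppressors Socs3 and Socs1 both at 7.32, and Marcksl1 at 4.13. With every library set to the same total of reads the medians of these 4 lists were 4.87, 4.58, 1.52 and 2.30.

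Antigen presentation split by class. All 14 measured MHC class I genes were higher at 4 h, with a median of 2.65, or 1.98 with the same total, and a percentile of 99.9 among the random lists. The peptide transporter gene Tap1 stood at 5.01 (4.61 to 5.41), the class I transactivator gene Nlrc5 at 4.71 (4.12 to 5.30) and the immunoproteasome gene Psmb8 at 2.94 (2.22 to 3.66). H2-Q4 stood at 4.89, but H2-Q genes are near copies and the counting that could split their reads is not given in the sources used here. None of the 11 measured MHC class II genes was called either way, with a median of 0.20 that turned to −0.47 with every library set to the same total of reads. H2-Ab1, Cd74, H2-Eb1 and H2-Oa had log2 fold changes of 0.79, 0.50, 0.49 and 0.65. Of 28 genes of TLR receptors and TLR4 signalling, 12 were higher, with a median of 0.95, or 0.27 with the same total. Irak3, a brake on this signalling, stood at 4.07 (3.76 to 4.37), the LPS co-receptor gene Cd14 at 2.84 (2.79 to 2.89) and Tlr1 at 2.42. Tlr3, a receptor for double-stranded RNA, had 1 read at 0 h, and the ratio of pooled reads was 213 with a 95% counting interval of 37.6 to 8465.

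Immediate-early genes went both ways in ExoCAGE at 4 h, with 8 of 20 higher, 4 lower and a median of 0.67, or −0.0027 with the same total. The phosphatase genes Dusp2 and Dusp1 stood at 3.76 and 2.91 and the transcription factor gene Atf3 at 3.01. The transcription factor genes Myc, Fos, Egr2 and Jun stood at −2.26, −2.06, −1.87 and −1.63. Of 25 cell cycle genes, 13 were lower and 2 higher, with a median of −1.32, or −1.98 with the same total, and a percentile of 0.06. The replication licensing genes Mcm7 and Mcm2 stood at −2.88 and −2.84. Cdc6, which loads the same helicase, and the mitotic checkpoint gene Bub1 were near 0 at 4 h, each with a 95% counting interval of 3.33 to 817 for the ratio of 0 h to 4 h reads. Against their list, the proliferation marker Mki67 stood at 2.45 (1.21 to 3.69) and the thymidylate synthase gene Tyms at 1.39 (1.21 to 1.56).

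Metabolic and housekeeping lists were read in ExoCAGE at 4 h as well. Cholesterol synthesis had 3 of 22 genes higher, 1 lower and a median of 0.47, or −0.20 with the same total. The isoprenoid enzyme gene Idi1 and the sterol regulator gene Srebf2 stood at 2.30 and 1.59, Hsd17b7 had 1.29 without a call, and Dhcr7, the enzyme that makes cholesterol from 7-dehydrocholesterol, stood at −3.79 (−4.05 to −3.54). Glycolysis and hypoxia had 4 of 21 higher and a median of 0.48, or −0.20 with the same total, with the phosphofructokinase genes Pfkp and Pfkfb3 at 2.17 and 2.11. Lysosome and phagocytosis had 2 higher and 2 lower of 25, with a median of −0.24, or −0.91 with the same total, and a percentile of 0.03. Its extremes were the high-affinity IgG receptor gene Fcgr1 at 3.21 and the low-affinity receptor gene Fcgr3 at −1.36. Ribosomal protein genes had 1 of 27 higher, Rpl13 at 2.17, and a median of −0.02, or −0.70 with the same total.

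Markers of cell types moved as follows at 4 h in ExoCAGE. Among macrophage markers 3 of 11 were higher and 2 lower, with a median of −0.15, or −0.82 with the same total. The scavenger receptor gene Marco stood at 3.41 and the phagocytic receptor gene Mertk at 2.64, while the haemoglobin receptor gene Cd163 stood at −2.89 and the growth factor receptor gene Csf1r at −1.10. Of 8 dendritic cell markers, the transcription factor genes Irf8 and Batf3 stood at 3.12 and −1.65 and 6 were not called. The single measured T cell, NK cell and stromal markers, of 11, 8 and 10 listed, stood at 3.38, 3.35 and 3.02. They were Lck, Klrk1 and Pdgfrb, with 13.1, 99.8 and 18.5 normalised reads at 4 h. No gene of these lists reached 10 normalised reads at 0 h, so each was measured only through its 4 h level. The 2 B cell and 2 mast cell markers had medians of −1.07 and −0.79, and no erythroid marker was measured. Of 12 neutrophil markers, Lcn2, which binds bacterial siderophores, stood at 2.77 (2.67 to 2.86) and 11 were not called, among them S100a9 at 0.92. Lcn2 is also known as an acute-phase gene. The most abundant neutrophil marker at 0 h was S100a8, with 3731 normalised reads, the most abundant macrophage marker was Csf1r, with 4990, and the most abundant dendritic cell marker was Itgax, with 1403. The median marker had 225, 541 and 25.5. The highest marker at 0 h was Cd22, at 89.0, for B cells, Klrk1, at 9.52, for NK cells, Prss34, at 42.8, for mast cells and basophils, Thy1, at 2.84, for T cells, Alas2, at 0.412, for erythroid cells and Col1a2, at 2.33, for stromal cells.

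Over all 9479 genes tested in ExoCAGE at 4 h, 1716 were higher and 1113 lower by at least 2-fold in every pairing of libraries. Splits that mixed the 0 h and 4 h libraries called 12 genes each. Their pairings across times ran in opposite directions, so a gene that changed with time could hardly be called in them. Higher genes made up 60.7% of calls with the deposited scaling and 28.7% with every library set to the same total of reads, 1065 higher against 2642 lower. That scaling, chosen after the data were seen, moved the median log2 fold change of the tested genes from −0.01 to −0.67. The median-ratio rescaling, planned before, gave 1713 higher and 1106 lower.

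**Figure D1:**
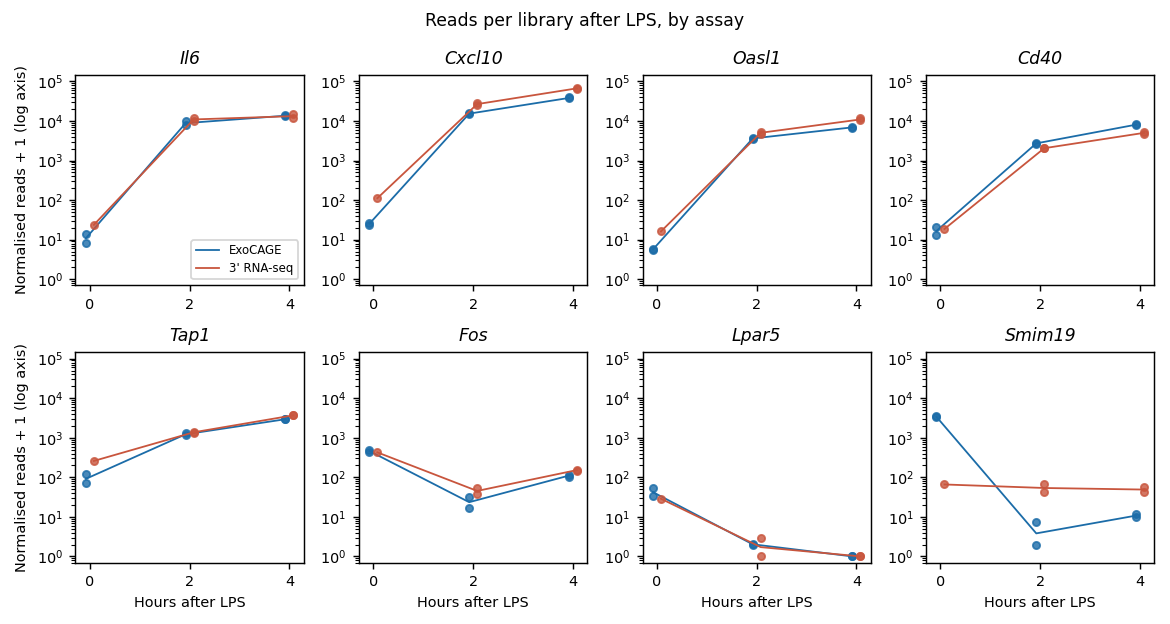
Normalised reads plus 1 (log axis) of 8 genes against hours after LPS, with a point per library and a line through the means on the log scale, for ExoCAGE in blue and 3' RNA-seq in red. Il6, Cxcl10, Oasl1, Cd40 and Tap1 stood above 0 h at both later times in both assays, Fos and Lpar5 stood below, and Smim19 stood below 0 h in ExoCAGE while its 3' log2 fold change at 4 h was −0.43.

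At 2 h in ExoCAGE cytokine and interferon-stimulated genes again stood highest over 0 h. Il6 stood at 9.67 (9.12 to 10.22), Oasl1 at 9.32, Cxcl10 at 9.25, Gbp5 at 8.89, Ifit1 at 8.80 (8.23 to 9.36), Cmpk2 at 8.64 (7.59 to 9.69) and the TNF family gene Tnfsf15 at 8.27. Il23a, a subunit of interleukin 23, had 0 reads at 0 h and was at least 356-fold higher at 2 h and at least 14.9-fold higher at 4 h. Smim19 stood at −9.79 (−10.77 to −8.81), the lysophosphatidic acid receptor gene Lpar6 at −5.67, Arhgap25 at −4.82 and the activating receptor gene Cd300lb at −4.48. The receptor gene Mrgpre and the clock output gene Dbp had 0 reads at 2 h and were at least 24.3-fold and 13.4-fold lower.

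Of the lists at 2 h in ExoCAGE, all 37 interferon-stimulated genes, 30 of 34 cytokines and chemokines, 17 of 24 NF-kB genes, 15 of 18 maturation genes and 9 of 14 MHC class I genes were higher, with medians of 4.10, 5.37, 2.67, 3.02 and 1.27, or 3.60, 4.91, 2.11, 2.48 and 0.72 with the same total. TLR genes had 8 of 27 higher and a median of 0.50, or −0.05 with the same total. Immediate-early genes had 5 of 20 higher, 4 lower and a median of 0.91, or 0.36 with the same total. Dusp2, Jund and Junb stood at 3.87, 2.16 and 1.94, with Fos at −4.30 (−4.86 to −3.74), Myc at −2.97 and Egr2 at −2.62. Cell cycle genes had 2 of 27 higher and 3 lower, with a median of −0.48, or −1.03 with the same total, and Mki67 at 4.46 (3.43 to 5.49). No MHC class II gene was called among 11, and the medians were 0.41 for MHC class II, 0.20 for cholesterol synthesis, 0.18 for glycolysis and hypoxia, −0.11 for lysosome and phagocytosis and 0.11 for ribosomal proteins. With the same total these 5 medians were −0.14, −0.35, −0.37, −0.67 and −0.44.

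Over 9401 genes tested at 2 h in ExoCAGE, 1122 were higher and 739 lower, and the splits that mixed 0 h and 2 h called 13 and 9. Higher genes made up 60.3% of calls, and 27.6% with the same total of reads, which moved the median from −0.01 to −0.56. Without the second 0 h library 1687 genes were higher, and without the first or the second 2 h library 1109 or 1129 were lower.

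**Figure D2:**
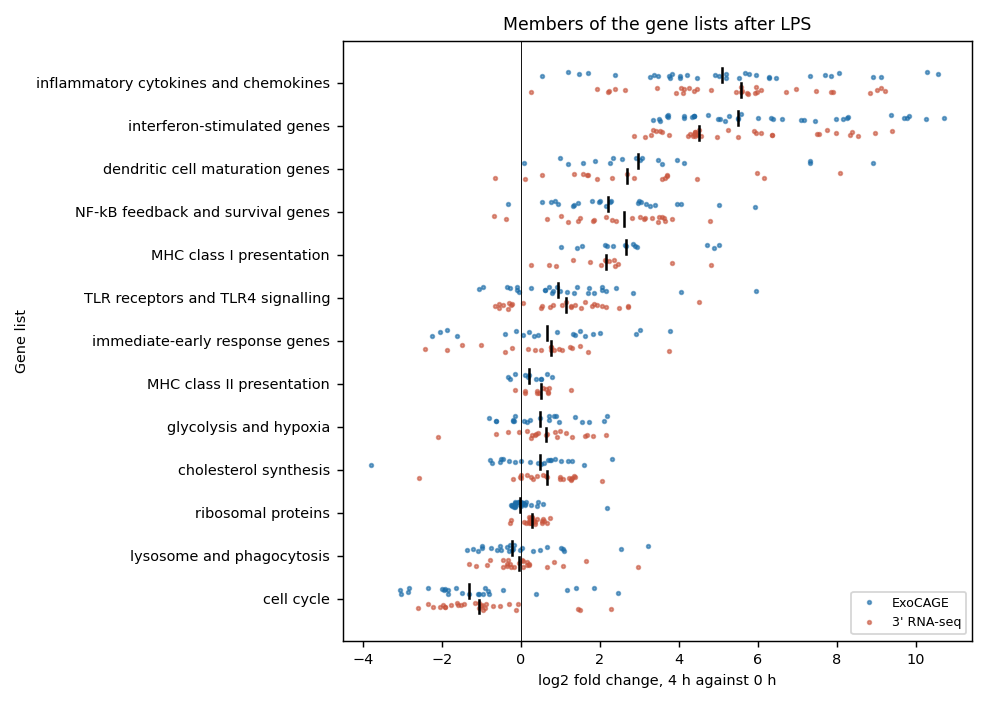
Log2 fold change at 4 h against 0 h, on the horizontal axis, of each measured member of 13 gene lists, with ExoCAGE in blue, 3' RNA-seq in red and a black bar at each median. Cytokines and interferon-stimulated genes lay farthest right, with medians of 5.10 and 5.50 in ExoCAGE, and cell cycle genes farthest left, with −1.32.

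The same question was put to 3' ends. At 4 h, Oasl1 stood at 9.41 (9.33 to 9.49), Cxcl10 at 9.23 (9.19 to 9.26), Il6 at 9.13 (8.96 to 9.30), Rsad2 at 8.98, Ptgs2 at 8.85, the activation marker Cd69 at 8.56 and Ifit2 at 8.54 on the log2 scale. Nos2 had 2 reads at 0 h and a pooled ratio of 950 (95% counting interval 263 to 7848). The 6 genes with the largest falls, ranked by their smallest fall over the pairings, all belonged to the 14 genes whose reads lay almost wholly in the single 0 h library. They were Ecel1, the ubiquitin pathway gene Ufd1, the mitotic kinesin gene Kif20a, the lipid kinase gene Pik3c2b, Ccdc77 and Terb2. Ecel1 had a ratio of 0 h to 4 h reads of 2684 (95% counting interval 743 to 22169). Ufd1 stood at −8.79 and Pik3c2b at −8.50. Kif20a was at least 162-fold lower, Ccdc77 at least 86.1-fold and Terb2 at least 73.9-fold. In ExoCAGE, Ufd1 stood at 0.17 (−0.01 to 0.36) at 4 h, and Ecel1 and Terb2 had 0 normalised reads in both 0 h libraries.

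Lists at 3' ends at 4 h gave all 37 interferon-stimulated genes higher with a median of 4.52, and 33 of 34 cytokines and chemokines with 5.57, or 5.50 with 1 gene at its bound. NF-kB genes had 20 of 24 higher and a median of 2.60, with Nfkbiz at 4.79, Cflar at 3.82 and the survival genes Bcl2a1a and Bcl2a1d, near copies and so uncertain, at 3.66 and 3.61. Maturation genes had 16 of 19 higher and a median of 2.69, with Cd40 at 8.07, Socs1 at 6.15, Socs3 at 5.97 and Marcksl1 at 4.45. MHC class I had 11 of 14 higher and a median of 2.15, with Nlrc5 at 4.83, Tap1 at 3.83, Tapbpl at 2.46 and Psmb10 at 2.39. MHC class II had 1 of 12 higher, H2-Eb2 at 1.26, and a median of 0.49, or −0.25 with the same total, with H2-Ob at 0.71. TLR genes had 15 of 29 higher and a median of 1.13, or 0.39 with the same total, with Tlr3 at 4.51, Cd14 at 2.72, Tlr1 at 2.70 and the adaptor gene Myd88 at 2.48. With the same total the medians of interferon-stimulated genes, cytokines, NF-kB genes, maturation genes and MHC class I were 3.78, 4.86, 1.86, 1.97 and 1.41.

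Immediate-early genes at 3' ends had 5 of 20 higher, 3 lower and a median of 0.76, or 0.019 with the same total, with Dusp2 at 3.75 and Klf6 at 1.71 against Egr2 at −2.45, Myc at −1.87 and Fos at −1.49. Cell cycle genes had 10 of 28 lower, 3 higher and a median of −1.06, or −1.78 with the same total, with Mcm2 at −2.60, the mitotic kinase gene Aurkb at −2.35 and Mcm7 at −2.24 against Ccne1 at 2.28, Mki67 (1.44 to 1.56) and E2f8 at 1.44. Cholesterol synthesis had 7 of 22 higher and a median of 0.65, which turned to −0.093 with the same total of reads. Idi1 stood at 2.06, Sc5d at 1.34 and Dhcr7 at −2.60. Glycolysis and hypoxia had 6 of 21 higher and a median of 0.62, or −0.12 with the same total, with Pfkp at 2.16, Pfkfb3 at 1.83, Hk2 at 1.68 and the angiogenic factor gene Vegfa at −2.11. Lysosome and phagocytosis had a median of −0.06, or −0.81 with the same total, with Fcgr1 at 2.97, Fcgr2b at 1.66, Npc1 at −1.32 and Fcgr3 at −1.13. No ribosomal protein gene was called among 27, with a median of 0.27, or −0.47 with the same total, and Rpl27 at 0.73. Of the markers, Marco stood at 4.31, Mertk at 2.00, Lcn2 at 2.72, Irf8 at 1.79, Batf3 at −1.47 and the mast cell and progenitor factor gene Gata2 at −2.26. Cd163 had a ratio of 0 h to 4 h reads of 8.40 (1.98 to 75.3).

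At 2 h the 3' ends ranked Il6 first, at 8.85 (8.76 to 8.95), then Il23a at 8.71, Ptgs2 at 8.39, Oasl1 at 8.29, Tnfsf15 at 8.07, Cxcl10 at 7.90 and the neutrophil chemokine gene Cxcl1 at 7.79. The interferon beta gene Ifnb1 had 0 reads at 0 h and was at least 166-fold higher at 2 h and at least 29.0-fold higher at 4 h. The nucleoside transporter gene Slc29a2 and the protease gene Tmprss4, both among the genes of the 0 h library, were at least 252-fold and 117-fold lower. All 37 interferon-stimulated genes, 33 of 34 cytokines and chemokines, 22 of 24 NF-kB genes, 14 of 19 maturation genes, 5 of 14 MHC class I genes and 12 of 29 TLR genes were higher, with medians of 3.12, 5.66, 2.96, 2.80, 0.87 and 0.83. With the same total these 6 medians were 2.51, 5.05, 2.34, 2.18, 0.25 and 0.21. Of the 28 cell cycle genes, 2 were higher and 3 lower, with a median of −0.38, or −0.99 with the same total. Immediate-early genes had 7 of 21 higher, 4 lower and a median of 0.37, or −0.23 with the same total. The medians of MHC class II, cholesterol synthesis, glycolysis and hypoxia, lysosome and phagocytosis and ribosomal proteins were 0.57, 0.30, 0.21, −0.08 and 0.35, or −0.05, −0.32, −0.41, −0.70 and −0.28 with the same total. Macrophage markers had 1 of 11 higher and a median of 0.07, which turned to −0.55 with the same total of reads. Dendritic cell markers had 3 of 10 higher and a median of 0.71 at a percentile of 99.6, or 0.098 with the same total. Mast cell markers had none of 5 called and a median of 0.79 at a percentile of 99.2, or 0.17 with the same total. In ExoCAGE at 2 h none of 8 dendritic cell and none of 3 mast cell markers was called. Their medians there were 0.054 and −0.23 at percentiles of 65.3 and 70.8. At 3' ends at 4 h these lists had medians of 0.021 and −0.13 at percentiles of 72.5 and 78.2.

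At 3' ends 1239 of 10524 genes were higher and 1148 lower at 2 h, and 1677 of 10639 higher and 1453 lower at 4 h. Splits that mixed times called 111 and 162 genes at 2 h and 260 and 185 at 4 h. Each set 1 later library against the other later library and the 0 h library. The pairing with 0 h is itself a contrast of times, so these counts cannot be set beside those of the ExoCAGE splits. In the ExoCAGE splits the pairings across times ran in opposite directions, which keeps out genes that changed with time. Higher genes made up 51.9% of calls at 2 h and 53.6% at 4 h, and 20.1% and 19.3% with the same total of reads, which moved the medians to −0.62 and −0.76. Every 3' comparison with 0 h rests on the single 0 h library. Without the genes of 1 library the 4 h counts were 1676 and 1439. With the median-ratio rescaling the 4 h counts were 1672 and 1443.

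Between 2 and 4 h the interferon-stimulated genes stood higher still. In ExoCAGE 26 of 37 were higher at 4 h than at 2 h, with a median log2 fold change of 1.44, and at 3' ends 27 of 37 with 1.75. Of the cytokines 8 of 34 were higher and 4 lower in ExoCAGE and 6 higher and 4 lower at 3' ends, with medians of 0.51 and 0.28 at percentiles of 100 and 99.4. In ExoCAGE 7 of 14 MHC class I genes were higher and 6 of 22 cell cycle genes lower, with medians of 1.19 and −0.70. The 3' medians of these lists were 1.16 and −0.93. In all, 413 of 8918 genes were higher and 241 lower in ExoCAGE, and 574 of 10169 higher and 338 lower at 3' ends. ExoCAGE splits that mixed these times called 13 and 40 genes and 3' splits called 12 each. The share of higher calls was 63.2% in ExoCAGE and 62.9% at 3' ends, against 54.0% and 52.5% with the same total of reads. ExoCAGE counts of higher genes were 625 and 914 without the first or second 2 h library, and its counts of lower genes were 433 and 450 without the first or second 4 h library and 459 and 416 without the first or second 2 h library. The 3' counts of lower genes were 522 and 610 without the first or second 4 h library and 512 without the second 2 h library.

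Fold changes from the 5' and the 3' end were then set side by side, each computed within its own table because the tables were normalised separately. Cd40, Il6, Oasl1, Ptgs2, Rsad2 and Cxcl10 were higher, and Lpar5, Lpar6, Cd300lb and Arhgap25 lower, in both assays at 4 h. Of 9125 genes tested in both at 4 h, 1121 were higher in both against 267 for independent lists, 682 were lower in both against 125, and 12 were called in opposite directions. The Spearman correlation across genes was 0.791 and the Pearson correlation 0.840. Genes are not independent replicates, so neither has a p-value. At 2 h, with 9044 genes, 797 were higher in both against 132, 456 lower in both against 65.2, and 5 went in opposite directions, with a Spearman correlation of 0.754. For 4 h against 2 h, 287 of 8535 were higher in both against 22.2, 119 lower in both against 6.31, and none went in opposite directions, with a Spearman correlation of 0.759.

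The widest gaps between the assays lay in single genes. At 4 h the nicotinamide riboside kinase gene Nmrk1 stood at 4.86 in ExoCAGE and −0.87 at 3' ends, the retromer gene Vps26b at 2.74 and −2.78, and Fbxo42 at 5.10 and 0.13. The log2 fold change of Cand1, a regulator of ubiquitin ligases, was 5.03 greater in ExoCAGE. Ufd1, at 0.17 and −8.79, was among the 14 genes of the 0 h 3' library. In the other direction Smim19 stood at −8.30 in ExoCAGE and −0.43 at 3' ends, the vesicle fusion gene Vamp1 at −3.68 and 2.46, and Znrf2 at −6.02 and −0.41. Taok1 stood at 1.25 and 6.30. Apobr stood at 0.03 in ExoCAGE with a gap of −6.48 to its 3' value and borders Il27, itself at 7.46 at 3' ends, in the GRCm38 gene order. Znrf2 in ExoCAGE and Taok1 at 3' ends belonged to the genes whose reads lay almost wholly in 1 library. At 2 h the gaps were led by Ufd1, Kmt5c at 2.96 and −2.34, Nmrk1 at 4.13 and −1.02, Cbarp at 2.94 and −1.62 and Fbxo42 at 3.98 and −0.53, against Smim19 at −9.79 and −0.30, Znrf2 at −6.67 and −0.08, Tmem60 at −1.39 and 4.82, Rad51d at −1.76 and 4.09 and Apobr at 0.51 and 6.23. Kmt5c in ExoCAGE and Tmem60 at 3' ends also had nearly all their reads in 1 library.

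**Figure D3:**
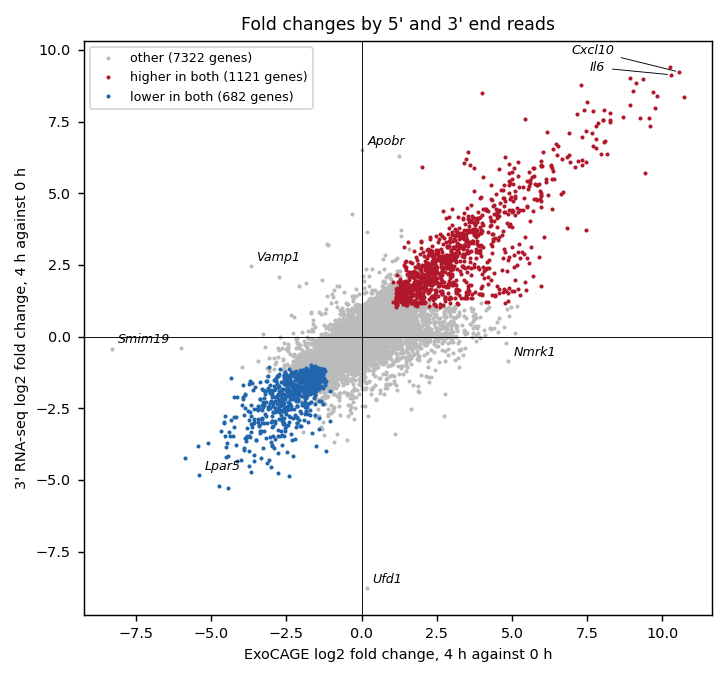
Log2 fold change at 4 h against 0 h of each gene tested in both assays, with ExoCAGE on the horizontal axis and 3' RNA-seq on the vertical axis. The 1121 genes higher in both are red, the 682 lower in both are blue, and Ufd1, Smim19, Apobr, Vamp1 and Nmrk1 lie far from the diagonal.

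Levels were compared across assays at each time, with the tables normalised separately. At 4 h Pate6 had a mean of 4160 normalised reads in ExoCAGE and 0 at 3' ends, Sspn 1387 and 0, Dnaja1 992 and 0, Fscn3 810 and 0, and Zfp143 58552 and 83.1. Conversely Wdr89 had 1.17 in ExoCAGE and 6495 at 3' ends, Akr1c19 0 and 1074, Ndst3 0 and 828, Palld 0 and 684, and Spata13 0 and 661. The Ndst3 mean came from the second 4 h library, with 1655 normalised reads against 1.29 in the first. The Spearman correlation of levels across genes was 0.673 over 8423 genes at 0 h, 0.754 over 8071 at 2 h and 0.766 over 8038 at 4 h. At 4 h 373 genes reached 10 normalised reads only in ExoCAGE and 1789 only at 3' ends, in tables of unlike depth.

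The 2 h and 4 h responses in ExoCAGE share their 0 h libraries, so their likeness was set against unchanged groups. Il6, Oasl1, Cxcl10 and Gbp5 were among the largest increases at both times. Over 9263 genes the Pearson correlation of the 2 fold changes was 0.900, against 0.41 in 20 simulations of unchanged groups with the shared controls. With 1 control library for each time it was 0.833 or 0.835. The covariance was 2.09 against 0.0286 simulated. No split kept 2 control libraries on each side.

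The deposited ExoCAGE windows of 5 bases gave the places where 5' ends gathered, on mm9 coordinates. In Cd40 the windows at chromosome 2, 164881171 to 164881175 and 164881176 to 164881180, were in both 2 h files, both 4 h files and neither 0 h file. In Cxcl10 the window at chromosome 5, 92777905 to 92777909, had the same pattern. Il6, whose window at chromosome 5, 30339681 to 30339685, was in all 6 files, gained 2 windows at 30339706 to 30339710 and 30339711 to 30339715 in all 4 files after LPS. Smim19 had windows at chromosome 8, 23587956 to 23587960 and 23587961 to 23587965, in both 0 h files and no later file. Its other windows, at 23581776 to 23581780 and 23581781 to 23581785, were each in 1 of the 4 h files and no other file. Lyz2, an abundant macrophage lysozyme gene, kept its window at chromosome 10, 116719327 to 116719331, in all 6 files. The files gave no strand, and no mm9 annotation was used here to place windows in exons or introns.

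Over the 6 files, 13689 to 17125 windows fell in 5584 to 6208 genes. A file shared 61.7% ± 4.48 of its windows with the other file of its time (SD over 6 directions, 55.7 to 67.8%). The shares were 54.4% ± 3.21 between 2 and 0 h, 51.1% ± 3.66 between 4 and 0 h and 59.4% ± 4.05 between 4 and 2 h, each over 8 directions. In both files of 4 h and neither of 0 h lay 2672 windows in 1309 genes, and 1504 windows in 1102 genes lay in both files of 0 h and neither of 4 h. Pairs of files that mixed 0 h and 4 h gave 257 to 512. At 2 h the counts were 1503 gained and 1247 lost against 370 to 492, and between 2 and 4 h 1200 gained and 712 lost against 303 to 858. Of 1469 genes with windows that were higher at 4 h in ExoCAGE, 729 gained a window, a share of 49.6% (exact 95% interval 47.0 to 52.2%). Of 807 lower genes 26 gained a window, 3.22%, and of 4955 others 483 did, 9.75%. Windows were lost in 301 of the lower genes, 37.3% (34.0 to 40.7%), in 82 of the higher genes, 5.58%, and in 669 of the others, 13.5%. Some genes had windows at both times. Of these, 211 of 893 higher genes, 23.6%, gained a window over 50 bp from every 0 h window. So did 14 of 222 lower genes, 6.31%, and 155 of 2859 others, 5.42%. Windows and calls came from the same libraries, so all of these shares partly restate the calls.

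**Figure D4:**
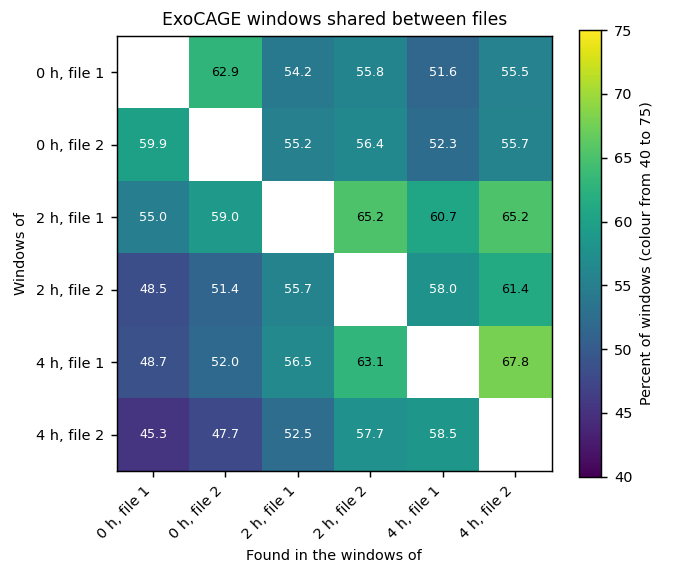
Percent of the ExoCAGE windows of each file (vertical axis) that overlapped a window of each other file (horizontal axis), with the colour scale from 40 to 75%. Files of the same time shared 55.7 to 67.8% and files of 4 h and 0 h 45.3 to 55.7%.

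In fly heads, full-length RNA-seq at 3 h was compared with 3' RNA-seq at the same time and with full-length reads at 15 h of zeitgeber time. The gene listed as gene_NM_001144309_NM_001144308_NM_078744_NM_001201758_NM_164540_NM_001014463_NM_001038783_NM_164542_NM_001201757_NM_164541 had 0.436 reads per base pair at 3 h and 4.22 at 15 h. The gene listed as gene_NM_164639_NM_057843_NM_001144320 had 0.359 at 3 h and 2.88 at 15 h. The gene listed as gene_NM_140627 had 7.72 at 3 h and 1.63 at 15 h, and gene_NM_001103759 had 2.46 and 0.0475. The files do not pair these identifiers with names, so the 13 fly gene lists, clock genes included, could not be used. Of 2480 genes, 2 were higher and 7 lower at 15 h by at least 2-fold with a pseudocount of 1 read per base pair. That pseudocount exceeded the median level of 0.222 at 3 h. With it no exact 2-fold change can pass the rule, as in 0 of 50 genes simulated without noise. A pseudocount of 0.01 with a minimum of 0.2, chosen after the data were seen, gave 36 higher and 38 lower. The Spearman correlation across 2335 genes between reads per base pair and the 3' score was 0.779. The number of reads behind these values is unknown, and each condition was a single library.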

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

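The tests of the genes carried by the 3' library of 0 h were chosen only after that result was seen. The other tests in this part were set before their results were seen.

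At 4 h against 0 h, 12 genes were called higher by one assay and lower by the other, every pairing of libraries in each assay going its own way, and at 2 h there were 5. At 4 h Hnrnpd, which binds AU-rich elements of mRNA, stood at 2.22 in ExoCAGE and −1.42 at 3' ends, Vamp1 at −3.68 and 2.46, Vps26b at 2.74 and −2.78, Amacr at 2.77 and −1.99, Clcn5 at 1.63 and −2.54, Tpx2 at −2.07 and 1.77, Cyren at −1.87 and 1.85, Rhbdd2 at 2.23 and −1.57, Ankhd1 at 2.32 and −1.41, Map3k2 at 2.15 and −1.38, Inpp4a at 1.37 and −1.32 and 1700017B05Rik at 2.45 and −1.18. At 2 h Rad51d stood at −1.76 and 4.09, Cbarp at 2.94 and −1.62, Ahdc1 at 2.90 and −1.55 and Hnrnpd at 1.60 and −1.12. Grpel2 was called higher in ExoCAGE and stood at −2.07 at 3' ends. The difference between the assays was not tested.

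The 3' library of 0 h held 14 genes far above every later 3' library, led by Ecel1, Ufd1 and Pik3c2b. Each of the 10 other libraries also held at least 1 gene of its own, from 1 to 7. These counts are not alike. The 3' library of 0 h alone had no second library of its time, so a gene that fell after LPS would also count there. In ExoCAGE 2 genes, Cd300lb and Smim19, stood that far above every later library in both 0 h libraries. Reads that a single library carries alone are a candidate explanation, which these counts cannot decide. A decrease after LPS stays open, because the 3 of these genes with at least 10 normalised ExoCAGE reads at 0 h had a median ExoCAGE log2 fold change of −2.41 at 4 h, too few genes to decide. Of these, Angptl4 had 0 reads at 4 h and was at least 11.8-fold lower, Snx24, which gave that median on the scale with 1 read added, had 3 reads and a ratio of 0 h to 4 h reads of 7.78 (95% counting interval 2.45 to 39.6), and Ufd1 stood at 0.17.

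In ExoCAGE 276 genes were higher at 4 h with under 0.5 log2 change at 3' ends. Fbxo42 at 5.10 and 0.13 and Ahctf1 at 4.09 and 0.06 had neither a new window nor an adjacent gene higher at 3' ends. Pacsin2 at 4.55 and 0.16, Vhl at 4.07 and 0.22 and Tor1b at 4.72 and 0.35 each had both. For these single genes windows were not required at both times. No new window can mean no window shared by the 4 h files, and a new window can lie in a gene with no 0 h window. File-to-file spread of the ExoCAGE counts was argued against, since splits that mixed 0 h and 4 h gave at most 3 such genes higher on 1 side. Those splits can hardly call a gene that changed with time. Spread at 3' ends was not covered, since the 3' change rests on a single 0 h library whose spread cannot be estimated. Reads of a neighbouring gene cannot be told apart from none: 44 of 273 genes, 16.1% (exact 95% interval 12.0 to 21.0%), adjoined a gene higher at 3' ends. That share equalled the median of random lists, which was the bound set in advance against this explanation. Its percentile with ties halved was 51.8, just past that bound. The interval also reached past the upper bound of 20.5% that these lists set. A start site used only after LPS may account for part, as 29.6% of 125 such genes with windows (21.8 to 38.4%) had a 4 h window over 50 bp from every 0 h window, against 120 of 599 genes higher in both assays (16.9 to 23.5%), although these intervals overlap. The windows came from the same libraries as the calls, with a threshold that is not given. A site below that threshold at 0 h cannot be told from a site not used.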

How the results depend on the processing

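The same-total rescaling, the edgeR and limma runs with and without the replicate block, the leaving out of genes of 1 library and the lower fly pseudocount were chosen only after the results were seen. Of the values that answer a comparison, 172 stayed close under the alternatives run and 120 moved. Of the others 2303 stayed close, 675 moved and 2 reversed. With the same total of reads, 23 of 67 list medians against 0 h changed sign. The median-ratio rescaling gave 1118 higher and 729 lower in ExoCAGE at 2 h against 0 h, and 1713 and 1106 at 4 h. At 3' ends it gave 1226 and 1157 at 2 h and 1672 and 1443 at 4 h. The 2 counted as reversed, since they lay outside the middle 95% of random lists, were the 3' medians of macrophage markers at 2 h, at −0.55, and of cholesterol synthesis at 4 h, at −0.093. With the number in the column name as a replicate block, edgeR on the ExoCAGE reads, at 1 residual degree of freedom, gave 1150 higher and 365 lower at 2 h, 2379 and 1792 at 4 h, and 255 and 129 for 4 h against 2 h, where without the block it gave 1539 and 780, 2578 and 2238, and 586 and 429. Deviations of libraries with the same number correlated from −0.17 to 0.25 between the ExoCAGE times and at −0.02 between 2 and 4 h at 3' ends. The highest value was that of 0 and 2 h. With so few libraries these values cannot decide whether libraries of the same number share a culture or batch. The edgeR block was not fitted at 3' ends, since leaving out the second 2 h column took the last residual degree of freedom. With limma on log2 values, which kept that column, ExoCAGE had 2110 higher and 1148 lower at 2 h, 2616 and 1888 at 4 h and 674 and 482 for 4 h against 2 h with the replicate block, and 2193 and 1319, 2682 and 2039, and 797 and 598 without it. At 3' ends limma gave 2379 and 1308 at 2 h, 2815 and 1977 at 4 h and 1869 and 1603 for 4 h against 2 h with the block, at 1 residual degree of freedom, and 2412 and 1350, 2884 and 2085, and 1732 and 1455 without it. Not run were the upper part of windows by score, since the files hold no score, and leaving out the only 3' 0 h library. Apart from fewer genes tested or libraries compared, the cause was not tested. In ExoCAGE at 2 h against 0 h, counts of higher and lower genes were 1772 and 1329 between the means and 491 and 159 at 4-fold, 696 and 1827 with the same total, and 292 lower with a minimum of 50. Without 1 library they lay from 1227 to 1687 higher (the highest without 0 h library 2) and 930 to 1129 lower (1109 and 1129 without 2 h library 1 and 2). At 4 h they were 839 and 292 at 4-fold, 1065 and 2642 with the same total and 2578 and 2238 with edgeR, with 505 lower at a minimum of 50 and 1710 lower between the means. Without 1 library they lay from 1844 to 2146 and 1340 to 1500. For 4 h against 2 h they were 646 and 444 with no filter, 772 and 559 between the means and 73 and 28 at 4-fold, with 129 lower at a minimum of 50 and 429 lower with edgeR. Without 1 library they lay from 563 to 914 (625 and 914 without 2 h library 1 and 2) and 416 to 459 (433 and 450 without 4 h library 1 and 2, 459 and 416 without 2 h library 1 and 2). At 3' ends at 2 h they were 524 and 245 at 4-fold and 731 and 2904 with the same total, with 2058 higher under edgeR and 1759 and 637 lower with no filter and a minimum of 50. At 4 h they were 789 and 385 at 4-fold, 913 and 3819 with the same total and 2822 and 2651 with edgeR, with 2220 and 859 lower with no filter and a minimum of 50. For 4 h against 2 h they were 944 and 650 between the means, 116 and 36 at 4-fold and 1454 and 1145 with edgeR, with 216 lower at a minimum of 50. Without 1 library the 3' counts lay from 1374 to 1428 and 1475 to 1558 at 2 h, 1908 to 1924 and 1859 to 1900 at 4 h, and 755 to 832 and 467 to 610 for 4 h against 2 h (522 and 610 without 4 h library 1 and 2, 512 without 2 h library 2). The correlation of fold changes between assays was 0.594 with no filter, 0.804 at a minimum of 50 and 0.813 by Pearson at 2 h, and 0.653, 0.837 and 0.840 at 4 h. Without 1 library it lay from 0.713 to 0.770 at 2 h and 0.759 to 0.804 at 4 h. The correlation of levels was 0.814, 0.853 and 0.857 at 0, 2 and 4 h with no filter, 0.739, 0.799 and 0.806 by Pearson, and 0.731 and 0.734 at 2 and 4 h at a minimum of 50. Windows within 50 bp were shared at 76.9% in the same time, 70.3% for 2 h and 0 h, 67.0% for 4 h and 0 h and 74.9% for 4 h and 2 h, with 831 in 0 h and not 2 h, 792 in 4 h and not 2 h and 435 in 2 h and not 4 h. In the fly, 4 genes were higher and 16 lower with a pseudocount of 0.2, 0 and 0 with 5 or at 4-fold, 0 and 3 with a minimum of 5 reads per base pair, and 36 and 38 with a pseudocount of 0.01 and a minimum of 0.2. The fly correlation was 0.904 with no filter, 0.858 at 5 times the minimum and 0.870 by Pearson. Read depth limits genes near 10 normalised reads.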

Other observations

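The 14 gene families here were chosen only after the results were seen, as were the single genes named in this part.

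Gene families were read at 4 h against 0 h, several of which share members with the fixed lists, such as Gbp5, Parp14, Socs1, Dusp1, Klf6 and Psmb8, and so partly restate them. All 10 measured guanylate-binding protein genes, interferon-induced GTPases, were higher in both assays, with median log2 fold changes of 6.04 in ExoCAGE, or 5.93 with 1 gene at its bound, and 5.45 at 3' ends, and all 7 Schlafen genes were too, with a 3' median of 4.84. Among them Slfn4 stood at 7.81 and 6.91. Of the PARP genes, 6 of 11 were higher and 1 lower in ExoCAGE and 7 of 12 higher and 2 lower at 3' ends, with Parp14 at 4.75 and 4.36. TRIM genes went both ways, with a median of 0.34 in ExoCAGE, or −0.23 with the same total of reads, and −0.07 at 3' ends, or −0.80 with the same total, and Trim30a at 4.02 and 4.26. Of the proteasome genes Psma and Psmb, 7 of 17 were higher in ExoCAGE and 9 of 17 at 3' ends.

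Falling families included the Ypel and arrestin-domain genes, with 4 of 7 lower and 1 higher in each assay and medians of −2.88 and −2.48. Arrdc3 stood at −3.91 and −3.89 and Ypel3 at −4.59 and −3.02. In the CD300 family of myeloid receptors 4 of 8 genes were lower in ExoCAGE and 3 of 9 at 3' ends, with medians of −1.51 and −0.97. Of 3 lysophosphatidic acid receptors, Lpar5 and Lpar6 were lower and Lpar1 higher, at 3.09 and 3.75. The glucocorticoid-responsive gene Tsc22d3 stood at −3.44 and −2.97. Suppressors of cytokine signalling, Kruppel-like factors, dual-specificity phosphatases, solute carriers, mitochondrial ribosomal proteins and chromatin enzymes of the Hdac and Kdm families had ExoCAGE medians of 1.62, 0.60, 0.26, −0.33, −0.26 and −0.07. Their 3' medians were 0.34, 0.44, 0.15, −0.28, −0.15 and −0.20. With the same total these medians were, in the same order, 0.98, −0.063, −0.40, −0.98, −0.93 and −0.74 in ExoCAGE and −0.38, −0.29, −0.58, −0.996, −0.87 and −0.93 at 3' ends.

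Cflar had windows at several places on chromosome 1. The window at 58770145 to 58770149 was in both 0 h files and no later file, its neighbour at 58770135 to 58770139 was in both 0 h and both 4 h files and neither 2 h file, and those at 58782965 to 58782969 and 58783340 to 58783344 were in all 4 files after LPS and neither 0 h file. A further window at 58810950 to 58810954 was in 1 of the 2 h files and both 4 h files. Cmpk2 gained a window at chromosome 12, 27154250 to 27154254, and Arrdc3 lost one at chromosome 13, 81022668 to 81022672.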
